A study of Homo sapiens with 20 samples.

How the data were processed

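RNA was measured in classical monocytes from the blood of 10 subjects with asthma, with 2 libraries per subject, 1 cultured for 24 h with plain HDL and 1 with HDL enriched with recombinant human SAA1. Per the labels' protocols, the cells were enriched by negative selection and then flow sorted for CD45 and CD14 without CD16. Libraries were made from 100 to 500 ng of total RNA with a stranded total RNA kit and ribosomal RNA removal, per the labels' protocols, and read in pairs. Reads were checked with FastQC, trimmed with cutadapt if required, aligned to the genome with HISAT2 2.1.0 and counted per gene with featureCounts in the GENCODE 25 annotation of GRCh38, using only uniquely mapped pairs, all per the labels' protocols. The labels do not give the strand setting of the counting. The authors deposited a single table of raw counts per gene for the 20 libraries, in whole numbers, with no normalized values. 4 copies of the U1 small nuclear RNA gene on chromosome 1 (RNU1-1 to RNU1-4) held counts within 0.405% of each other in every library, so reads of near-identical genes may be shared out between copies there despite the stated use of unique pairs. Per the labels' protocols, the authors kept genes with CPM above 1 in a share of at least 0.5 of the samples and compared the treatments in limma-voom with TMM scaling, and no subject term is stated there.

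Each library was assigned to its group (HDL or HDL+SAA1) and its subject by its title. The series labels carry an individual tag that differs between the 2 libraries of a subject and was taken as a library name, as it heads the columns of the table. Of 58037 entries 57433 were matched by identifier without version to GENCODE 29, which gave positions, lengths and overlaps, and 562 entries, on the Y chromosome or of XIST, were left out to keep the subjects' data private. The total count per library was 42166007 to 114396685 in the HDL group and 26424481 to 98386445 in the HDL+SAA1 group, and with the TMM factor included 1 CPM stood for at least 15.3 counts. No 2 libraries of a group held the same data, as the smallest chi-square per degree of freedom over 90 pairs was 128.

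Genes with CPM above 1 in at least 10 libraries were tested, 15143 in all, in R 4.3.3 with edgeR 4.0.16. Counts were scaled by TMM and fitted with glmQLFit with robust priors, with treatment as the only term, and tested by glmQLFTest with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are of HDL+SAA1 over HDL and their standard errors were taken from the coefficient and its F value. The levels in CPM use TMM-scaled library sizes, with a prior count of 2 where they are on the log2 scale. The 48 gene lists cover known responses of monocytes to SAA and HDL, lipid metabolism, stress, RNA quality and markers of other blood cells, and 925 of their 931 genes were found in the table. Lists with at least 3 tested members were tested by camera in limma 3.58.1 on voom values with a preset correlation of 0.01. For list members, adjustment over all genes was used, and adjustment over the list alone was given where it differed. Composition was compared by an exact permutation test of the paired differences (all 1024 sign flips, smallest two-sided p 0.00195) over 16 measures. The genes named were, per direction, the 12 largest log2 fold changes among genes past the threshold with the same direction in at least 8 of 10 subjects and a mean of at least 2 CPM, and per list the up to 4 members with the smallest p, which excluded immunoglobulin and T cell receptor segments and genes without a symbol. Genes named outside this rule were named after their values were seen. They are marked so, except neighbours and overlapping genes (such as WTAPP1, LIF, IL1RN and SERPINB7) and genes named for how reads map to them. Some list members that changed are not reported here by name. Of 288 genes chosen for naming, 103 overlap another tested gene, 80 on the other strand and 35 on the same strand. These overlaps are of whole gene spans, introns included, and shared exons were not checked.

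The numbers of the titles were taken to pair the libraries because each title gives the subject. This was checked before the fits were compared. The deviations from the group means of the 2 libraries of a subject correlated at 0.303 to 0.615 (median 0.443), over 0.1 in 10 of 10 pairs, against a median of -0.0651 for libraries of different subjects. As no subject term is stated in the labels, the fit without it was kept as planned. The fit with the subject as a block, which uses the pairing, is given where it changes a call and for some further genes. Log2 fold changes, standard errors and rankings are of the fit without the block unless stated.

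The steps were tested on simulated data with the means, spread and library sizes of the real libraries and 14971 genes, of which 50 each were changed by 1.5, 2, 4 and 8-fold. For HDL+SAA1 against HDL the fit without the block called 54% of the 1.5-fold, 88% of the 2-fold, 96% of the 4-fold and 84% of the 8-fold changes, and 5.85% of its calls were unchanged genes. With the block these shares were 46%, 84%, 96% and 84%, with 4.91% unchanged genes. Each simulated library was drawn on its own without an effect of subject, unlike the real pairs. Far fewer genes were changed than were called in the real data. These shares therefore do not show how the fits with and without the block perform on the paired libraries.

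The alternatives tried were the subject as a block, DESeq2 1.42.0 with and without the block, its size factors in edgeR, no filter beyond 1 count in all libraries together, filterByExpr, limma-voom without a block, with it and with the subject as a random effect, and priors without robust estimation. Each subject was left out in turn in both fits. The lists were also tested with an estimated correlation, with the block, without a filter and by fry, and composition with CPM by library size. After the data were seen, fits without HDL replicate 8, with scaling by library size alone and with multicopy RNA genes (ribosomal, mitochondrial ribosomal, 7SL, 7SK and small nuclear RNA) removed before scaling were added. The gene and list counts were also compared with 100 splits of the libraries, the real one included. Tables were handled with version 1.17.8 of the R package data.table and, in Python 3.11.15, with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.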

Results

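The series held 20 RNA-seq libraries of classical monocytes, white blood cells that carry the surface protein CD14 and lack CD16, sorted from the blood of 10 subjects with asthma. Monocytes of each subject were cultured for 24 h in medium with 2% fetal bovine serum and 4 µg/ml of high-density lipoprotein (HDL), the lipoprotein that takes up cholesterol from cells. In 10 libraries the HDL was plain (group HDL), and in 10 it had been enriched with 2 µg of recombinant human serum amyloid A1 (group HDL+SAA1), an acute-phase protein that circulates bound to HDL. The total gene count per library was 42166007 to 114396685 in the HDL group and 26424481 to 98386445 in the HDL+SAA1 group. The comparison asks which monocyte genes differ between HDL enriched with recombinant SAA1 and plain HDL. Plain HDL was the only control, as monocytes without HDL and monocytes given SAA1 alone were not analysed here. Effects of SAA1 bound to HDL, of unbound SAA1 and of anything else in the recombinant preparation therefore cannot be told apart.

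With SAA1 on the HDL, 15 of 20 inflammatory cytokine genes and 7 of 7 genes of neutrophil-attracting chemokines rose in the monocyte cultures, and 13 of 14 genes of MHC class II antigen presentation and 27 of 37 interferon-stimulated genes fell. As lists these 4 passed in camera (limma) with a preset correlation but not with an estimated one (adjusted p from 0.723 to 0.904). IL1A, which encodes the inflammatory cytokine interleukin 1 alpha, rose from 44.8 ± 66.5 to 702 ± 300 CPM (mean ± SD, n = 10 per group), and CXCL8, which encodes the neutrophil attractant interleukin 8, rose from 1268 ± 2248 to 13209 ± 6064 CPM. HDL replicate 8 held the highest HDL level of both, and without replicate 8 their log2 fold changes were 4.87 for IL1A, against 3.97, and 4.48 for CXCL8, against 3.38. With the subject as a block they were 4.80 for IL1A and 4.41 for CXCL8. SIGLEC1, a sialic acid receptor of macrophages that interferon induces, fell from 15.7 ± 15.4 to 0.740 ± 0.933 CPM, and HLA-DMB, which helps load peptides onto MHC class II, fell from 132 ± 48.7 to 14.3 ± 13.6 CPM. Each of these 4 genes moved in its direction in 10 of 10 subjects. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8220 of 15143 genes tested passed an adjusted p of 0.05, which was 54.3%, and 4145 of them were higher and 4075 lower with HDL+SAA1. Changes beyond 2-fold were called for 845 higher and 942 lower genes, and changes beyond 8-fold for 58 higher and 23 lower genes. With the subject as a block the test called 9823 genes (90 higher and 30 lower beyond 8-fold), 8183 of them shared in the same direction and 0 in the opposite one. Without TMM scaling the median log2 fold change of all genes moved to -0.22, and 23.7% of calls were higher, against 50.4% with TMM, so the directions given here are relative to the TMM centre. 1 library, HDL replicate 8, lay between the groups, at 0.552 on an axis of mean treatment difference where the HDL mean is 0 and the HDL+SAA1 mean is 1. The other HDL libraries lay between -0.336 and 0.276 and the HDL+SAA1 libraries between 0.629 and 1.39. Without it 8381 genes changed and 11 gene lists passed.

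The 12 largest rises by the rule for named genes ran from 3.77 to 4.82 on the log2 scale, and each was higher in 10 of 10 subjects. With the subject as a block these 12 ran from 3.84 to 5.95, the highest being IL36G. Without the block the largest was TFPI2, an inhibitor of serine proteases (ENSG00000105825.11, chromosome 7, 93885396 to 93890991, GRCh38), with a log2 fold change of 4.82 ± 0.87 (SE) and an edgeR adjusted p of 1.26e-04. The span of GNGT1, a G protein subunit (4.73), covers TFPI2 on the other strand. Their reads may not be separable, as the strand setting of the counting is not given in the sources used here. Overlap of their exons was not checked. Of the cytokine genes, IL19 of the interleukin 10 family changed by 4.48 ± 0.99, TNFSF15 of the tumour necrosis factor family by 4.30 ± 0.77, IL1A (ENSG00000115008.5, chromosome 2, 112773915 to 112784590) by 3.97 ± 0.60 and IL36G of the interleukin 1 family by 3.89 ± 1.004. IL36G rose by 5.95 on the log2 scale with the subject as a block, by 6.04 without both libraries of replicate 8 and by 6.09 without HDL replicate 8. IL19 changed by 2.70 in DESeq2. SERPINB2, an inhibitor of plasminogen activators, changed by 3.77 ± 0.96 and its neighbour SERPINB10 by 3.78 ± 0.95, although the 2 genes overlap on the same strand on chromosome 18. MMP10, a secreted matrix-degrading protease, changed by 3.80 ± 1.03 and overlaps the pseudogene WTAPP1 on the other strand, which changed by 3.61. The remaining 3 were SLCO4A1, an organic anion transporter (3.88 ± 0.54), its overlapping antisense transcript SLCO4A1-AS1 (4.03 ± 0.50) and the secreted protein gene MUCL1 (3.77 ± 0.86). Without replicate 8 the rise was larger for TFPI2 (5.62), TNFSF15 (5.04), IL1A (4.87), SERPINB2 (4.97), SERPINB10 (4.98), MMP10 (4.52), WTAPP1 (5.34), SLCO4A1-AS1 (4.63) and MUCL1 (5.24). It was smaller without replicate 6 for TFPI2 (4.23), MMP10 (2.95) and WTAPP1 (2.71) and without replicate 7 for IL19 (3.23), SERPINB2 (3.13) and SERPINB10 (3.14).

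The 12 largest falls ran from -4.60 to -3.17 on the log2 scale, and each was lower in 10 of 10 subjects. With the subject as a block these 12 ran from -4.68 to -2.35. SIGLEC1 (ENSG00000088827.12, chromosome 20, 3686970 to 3707128) changed by -4.60 ± 0.77 with an edgeR adjusted p of 6.00e-05, and IFIT1, an interferon-induced antiviral gene, by -3.65 ± 0.71. APOE (ENSG00000130203.9, chromosome 19, 44905754 to 44909393), the apolipoprotein that macrophages secrete with cholesterol, fell from 17.3 ± 18.6 to 1.51 ± 0.922 CPM, a log2 fold change of -3.56 ± 0.67. ACE, the angiotensin-converting enzyme, changed by -3.80 ± 0.42, ADA2, a secreted adenosine deaminase, by -3.33 ± 0.32 and ENPP2, which makes lysophosphatidic acid, by -3.32 ± 0.42. ALDH1A1, which makes retinoic acid, changed by -3.73 ± 0.42, and P2RY13, a receptor for ADP, by -3.17 ± 0.52. CD1E, a lipid antigen presentation gene, changed by -3.39 ± 0.80, with -2.35 under the block and -2.24 under limma-voom with the subject as a random block and -2.78 without replicate 7. HLA-DMB changed by -3.22 ± 0.45, the secreted matrix protein gene ANOS1 by -3.91 ± 0.52 and GGTA1, a transcribed pseudogene in the annotation, by -3.89 ± 0.62.

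**Figure D1:**
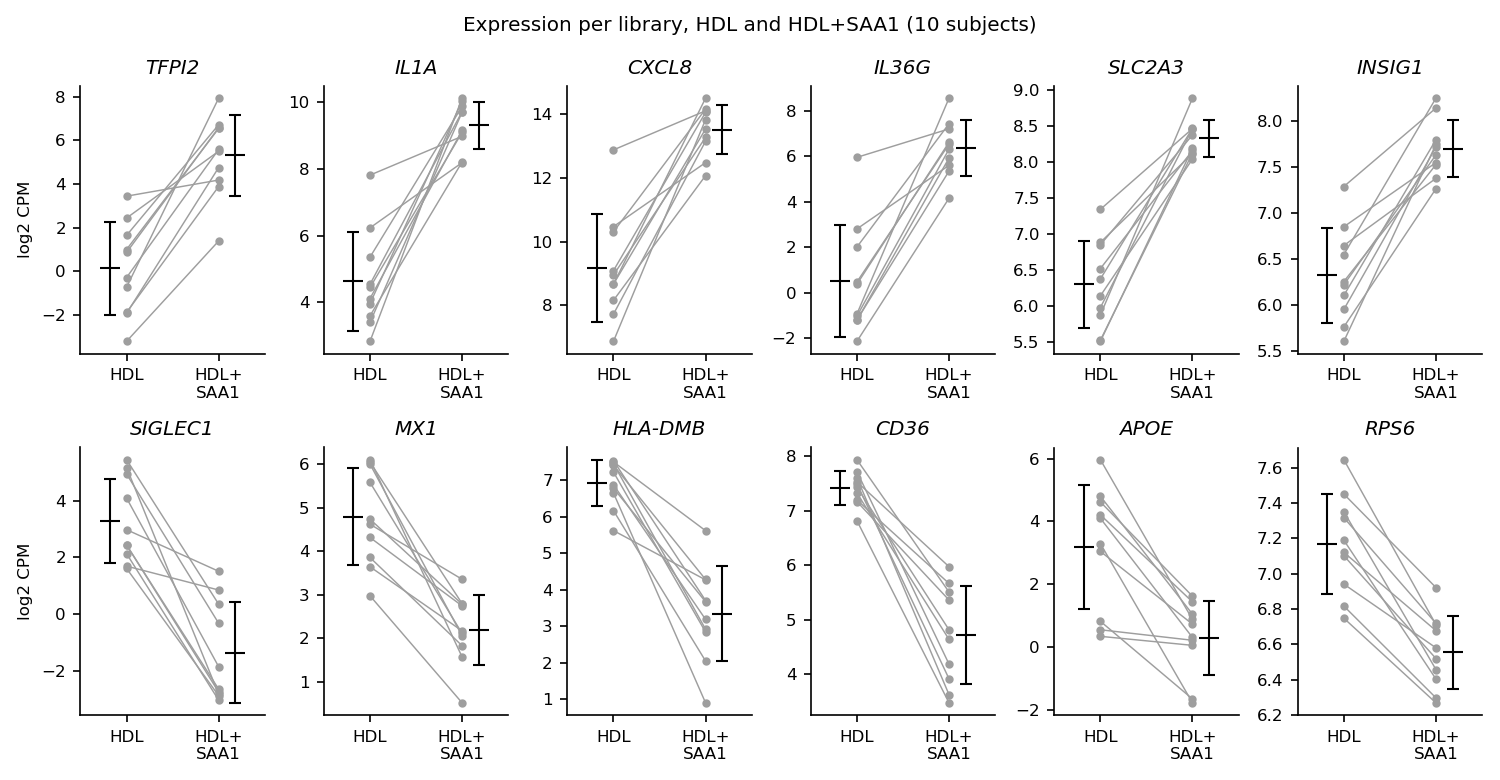
Log2 CPM (TMM-scaled counts-per-million values) of 12 named genes in the 20 libraries, with a grey line joining the 2 libraries of a subject and black bars at the group mean ± SD (n = 10 per group), each panel on its own y axis. TFPI2, IL1A, CXCL8, IL36G, SLC2A3 and INSIG1 were higher with HDL+SAA1 in 10 of 10 subjects, and SIGLEC1, MX1, HLA-DMB, CD36, APOE and RPS6 lower in 10 of 10.

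Gene groups were followed with 48 lists fixed before the data were examined, 46 of which had at least 3 tested members. Counts of members use edgeR's test over all 15143 genes, and the counts adjusted over the list alone were the same except where both are given. Of all genes 54.3% passed, 4145 of them higher and 4075 lower. A list with calls near these shares in both directions therefore does not stand out from all genes. In limma's camera with its preset correlation of 0.01, 11 lists passed, 8 upward and 3 downward. With an estimated correlation none passed at an adjusted p of 0.05, against 3 at an unadjusted p under 0.05, and fry passed 21. Other random splits of the 20 libraries passed a median of 9 lists in camera, and 29 of 100, the real one included, passed at least 11. In 11 lists, none of which passed, the median, the mean and the camera direction did not all have the same sign. These were the LXR, fatty acid, costimulation, eicosanoid, Fc receptor, unfolded protein, apoptosis, histone, type 2 asthma, classical monocyte and B cell lists.

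Of 20 tested inflammatory cytokine genes 15 rose and 1 fell. Besides IL1A, the rises included OSM, a cytokine of the interleukin 6 family (2.63 ± 0.40), and EBI3, a subunit of interleukins 27 and 35 (2.52 ± 0.37), and IL6, named after its value was seen, rose by 3.73 and with the subject as a block by 6.45 (by 5.43 without replicate 8), while IL18, an inducer of interferon gamma, fell from 9.80 to 1.54 CPM (-2.76 ± 0.29). All 7 tested genes of neutrophil-attracting CXC chemokines rose, with log2 fold changes of 3.64 ± 0.67 for CXCL3, 3.42 ± 0.70 for CXCL1, 3.38 ± 0.67 for CXCL8 and 3.35 ± 0.64 for CXCL2, and these 7 genes lie together on chromosome 4 between 73740506 and 74099293. Of 12 CC chemokine genes 7 rose and 0 fell, with CCL3 at 3.27 ± 0.70, CCL4 at 3.18 ± 0.63 and the monocyte attractant CCL2 at 2.01 ± 0.45. CCL3 shares its locus with an antisense transcript, and CCL4 and CCL4L2 (2.81 ± 0.66) are near-identical copies, so their single values are uncertain. The 5 CC genes that did not pass, named after their values were seen, were CCL1 (2.09), CCL5 (-0.59), CCL18 (0.59), CCL22 (-0.99) and CCL24 (-0.67). With the subject as a block 9 of the 12 rose, CCL1 (3.84) and CCL18 (0.77) with the 7, and 2 fell, CCL5 (-0.66) and CCL24 (-0.68). CCL1 also passed without replicate 5 (3.39), was 1.35 without replicate 7, and CCL18 passed without replicate 10 (0.76), while CCL22 was -0.23 without replicate 5 and -0.35 with the block. Without replicate 8 the rise was larger for CXCL1 (4.63), CXCL2 (4.39), CXCL3 (4.72), CXCL8 (4.48), CCL3 (4.50), CCL4 (4.26) and CCL4L2 (3.48). In limma's camera the cytokine list had an adjusted p of 6.35e-05 (0.819 with an estimated correlation), the CXC list 4.27e-04 (adjusted p = 0.819 with an estimated correlation) and the CC list 0.00917 (adjusted p = 0.867 with an estimated correlation).

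**Figure D2:**
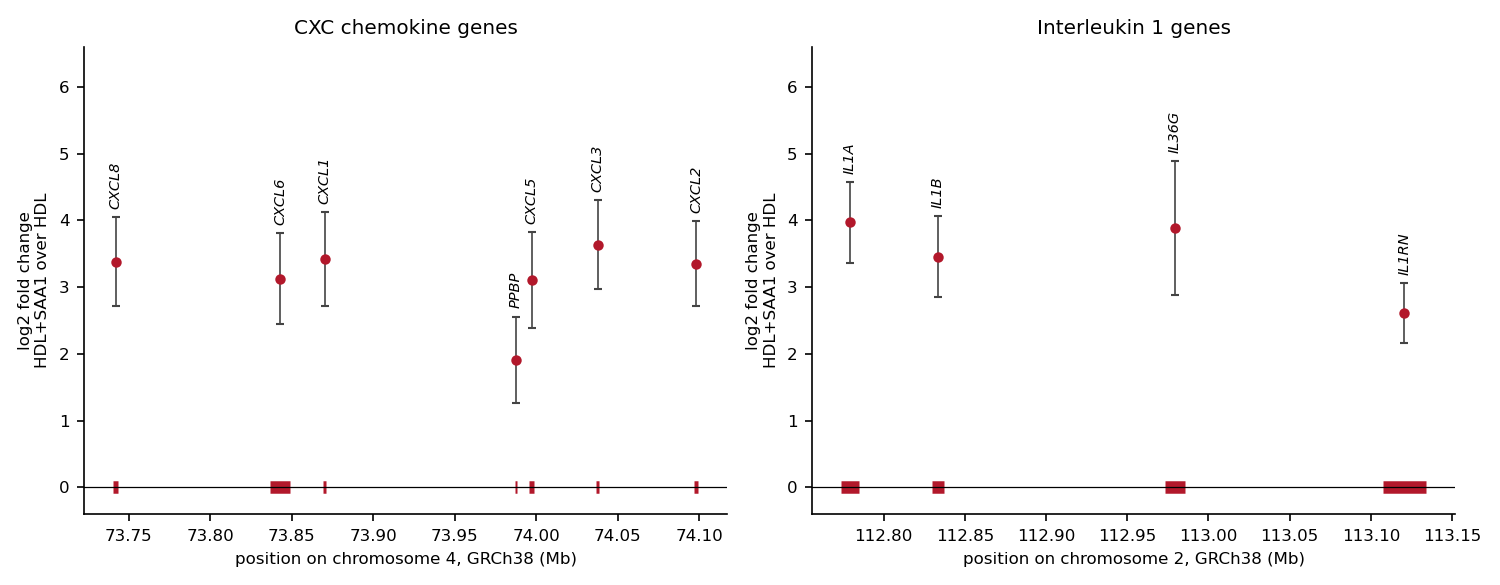
Log2 fold change (HDL+SAA1 over HDL, points, with bars of 1 SE from edgeR, n = 10 per group) of the tested protein-coding genes of 2 loci against their GRCh38 position in Mb, with thick marks on the 0 line at the extent of each gene and red for genes called higher. All 7 CXC chemokine genes on chromosome 4 and IL1A, IL1B, IL36G and IL1RN on chromosome 2 rose, from 1.92 to 3.97.

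Genes of NF-kB feedback and survival, induced by inflammatory signals and often acting to limit them, rose in 25 of 32 cases (26 adjusted over the list alone) and fell in 0. ZC3H12A, a ribonuclease that degrades cytokine mRNA, changed by 1.89 ± 0.17, IER3 by 1.87 ± 0.21, NFKBIZ by 0.98 ± 0.10 and NFKB2 by 0.86 ± 0.11. Of 21 genes of the SOCS and STAT3 response 13 rose (14 adjusted over the list alone) and 1 fell, the cytokine receptor subunit IL6ST (-0.38, named after its value was seen). SOCS3, a suppressor of cytokine signalling, changed by 1.51 ± 0.20, the kinase genes PIM1 and PIM2 by 1.78 ± 0.18 and 2.45 ± 0.30, and the survival gene MCL1 by 0.93 ± 0.13. Of 27 immediate early genes 15 rose and 4 fell. FOSL2 changed by 1.35 ± 0.13 and the phosphatase genes DUSP1 and DUSP2 by 2.05 ± 0.28 and 1.36 ± 0.16, while the 4 that fell, named after their values were seen, were FOSB (-1.46), JUN (-0.59), KLF2 (-1.14) and KLF4 (-1.40). The call was lost for JUN without replicate 1, 2, 3, 9 or 10 (-0.62 to -0.54) and KLF2 without replicate 1, 2, 3, 6, 7, 9 or 10 (-1.17 to -0.89). The camera adjusted p (limma) of the 3 lists was 8.19e-08, 0.00107 and 8.30e-04, and the adjusted p with an estimated correlation was 0.710, 0.723 and 0.710.

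Interferon-stimulated genes fell, with 27 of 37 lower and 3 higher. MX1, an antiviral GTPase, changed by -2.78 ± 0.42, HERC5, the ligase that attaches ISG15, by -1.83 ± 0.26, XAF1 by -2.30 ± 0.33 and PARP9 by -1.17 ± 0.13. XAF1 overlaps a transcript on the other strand. The 3 that rose were IDO1, the tryptophan-degrading enzyme (1.60 ± 0.35), and, named after their values were seen, ISG20 (1.56 ± 0.30) and GBP5 (1.15 ± 0.45). Significance was lost for GBP5 without replicate 1, 2, 5, 7, 9 or 10 (0.96 to 1.19), and with library size alone as the scaling (0.95). In limma's camera the adjusted p was 4.80e-05 (adjusted p = 0.904 with an estimated correlation).

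Of 14 genes of MHC class II presentation 13 fell, with a median log2 fold change of -2.48, and LGMN (0.29, edgeR adjusted p = 0.453, named after its value was seen) did not pass. CIITA, the transactivator of these genes, fell from 81.7 ± 26.1 to 19.2 ± 8.49 CPM (-2.09 ± 0.26), CD74, the invariant chain, from 613 ± 290 to 92.9 ± 40.2 CPM (-2.72 ± 0.33), HLA-DMA changed by -2.64 ± 0.32 and the lysosomal protease gene CTSS by -1.50 ± 0.14. With the subject as a block 13 fell and LGMN rose (0.55), as it did without replicate 1 (0.67). On chromosome 6, between 32439842 and 33087201, all 12 tested class II genes with an HLA symbol fell, with log2 fold changes of -3.22 to -2.43. Between them, the class I peptide supply genes TAP1 (0.17 ± 0.10), TAP2 (-0.07 ± 0.12) and PSMB8 (-0.23 ± 0.10) did not pass and PSMB9 fell (-0.53 ± 0.17), all 4 named after their values were seen. PSMB8 fell with the subject as a block (-0.23), without replicate 8 (-0.26), without HDL replicate 8 (-0.27) and with library size alone (-0.45). Reads of class II genes that differ between people can map unevenly to 1 reference, so the single values of HLA-DRB1, HLA-DRB5, HLA-DQA1 and HLA-DQB1 are in this respect less certain than those of HLA-DMA, HLA-DMB or HLA-DRA. HLA-DMA and HLA-DMB in turn overlap another tested gene on the same strand, which may share their reads. The camera adjusted p (limma) was 1.79e-06 (adjusted p = 0.723 with an estimated correlation). In the same libraries the mean log2 CPM of conventional dendritic cell markers differed by -0.76 ± 0.71 (mean ± SD, n = 10 pairs).

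**Figure D3:**
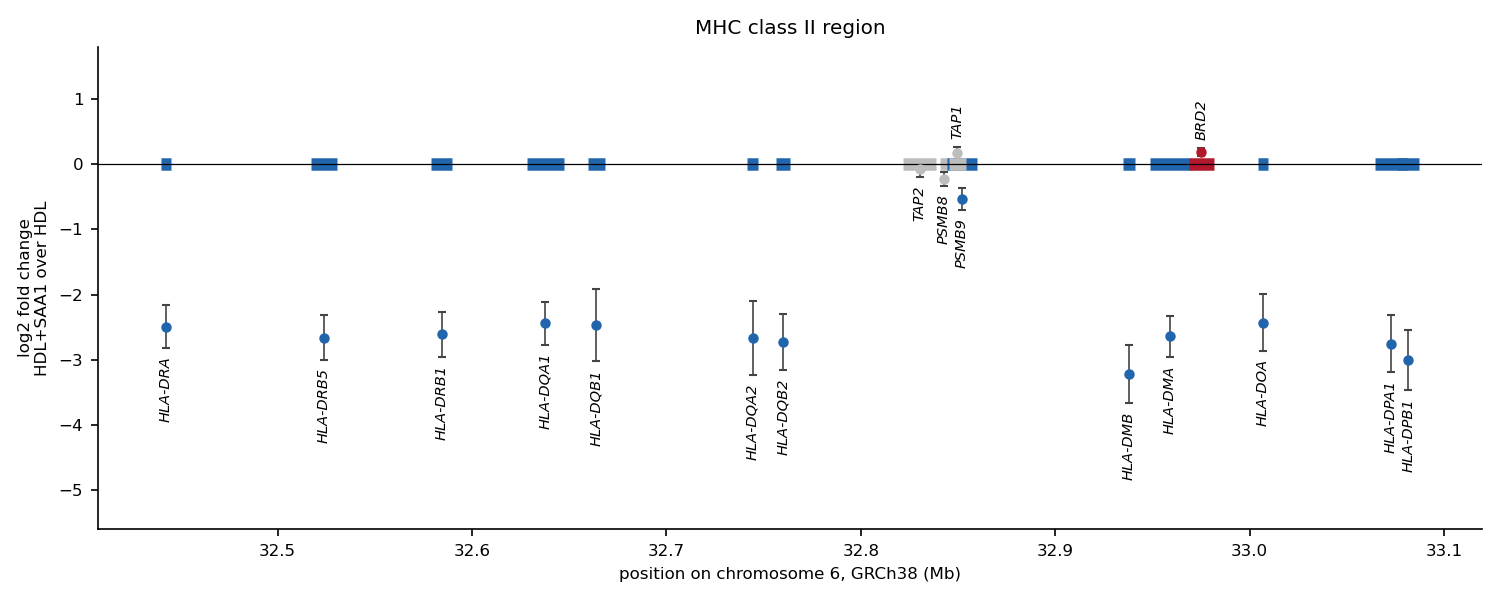
Log2 fold change (HDL+SAA1 over HDL, points, with bars of 1 SE from edgeR, n = 10 per group) of the tested protein-coding genes with a gene symbol in the MHC class II region against their GRCh38 position in Mb on chromosome 6, with thick marks on the 0 line at the extent of each gene. Blue marks genes called lower, red higher and grey not called. The HLA class II genes sit between -3.22 and -2.43, and TAP1, TAP2 and PSMB8 among them lie between -0.23 and 0.17.

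Genes of glycolysis and the hypoxia response rose in 25 of 30 cases. The glucose transporter genes SLC2A3 and SLC2A1 changed by 1.93 ± 0.21 and 1.77 ± 0.21, P4HA1, a collagen hydroxylase, by 1.46 ± 0.18 and NDRG1 by 1.54 ± 0.17. The 1 gene that fell, named after its value was seen, was HK3 (-1.10 ± 0.24). The list had the smallest camera adjusted p (limma), 6.95e-10 (adjusted p = 0.710 with an estimated correlation). VEGFA, the angiogenic factor that hypoxia induces, rose from 30.7 to 100 CPM (1.71 ± 0.23).

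Genes of lipid handling moved in both directions. Of 26 tested genes of cholesterol synthesis 13 rose and 3 fell (17 and 5 with the subject as a block). INSIG1, a sterol-regulated brake on that synthesis, changed by 1.32 ± 0.19, and the enzyme genes LSS and MSMO1 by 0.96 ± 0.20 and 0.93 ± 0.19, while the 3 that fell were TM7SF2 (-1.10 ± 0.19) and, named after their values were seen, PMVK (-0.48) and TMEM97 (-0.27). EBP, also named after its value was seen, fell with the subject as a block (-0.25). The camera adjusted p (limma) was 0.0459 (adjusted p = 0.904 with an estimated correlation), and the list no longer passed without replicate 1 (0.0508), 3 (0.0643), 6 (0.0571), 7 (0.0659) or 8 (0.0565), nor with library size alone as the scaling (0.0713). Targets of the LXR receptors and genes of cholesterol efflux split, with 5 of 17 higher and 5 lower, near the shares over all genes. ABCA1, the transporter that hands cholesterol to apolipoprotein A1, rose from 329 to 756 CPM (1.20 ± 0.15) and the lysosomal cholesterol exporter NPC1 changed by 0.65 ± 0.09, whereas APOE and its neighbour APOC1 (-3.09 ± 0.60, and -2.44 without replicate 1) fell. The other 3 that rose and 3 that fell, named after their values were seen, were SMPDL3A (1.33), NR1H2 (0.38) and LPCAT3 (0.27), and NR1H3 (-1.68), PLTP (-0.47) and NPC2 (-0.45), of which NR1H3 encodes LXR alpha. Of 17 genes of fatty acid synthesis and desaturation 5 rose and 4 fell, with rises of the acyl-CoA synthetase genes ACSL1 (1.96 ± 0.23) and ACSL4 (1.25 ± 0.19) and falls of ACACB (-1.52 ± 0.23) and GPAM (-1.06 ± 0.13). Named after their values were seen, FADS3 (1.37), ACSL3 (0.42) and ELOVL1 (0.26) rose too, and ME1 (-2.07) and ACACA (-0.57) fell too. Of 14 PPAR and lipid droplet genes 6 rose (7 adjusted over the list alone) and 3 fell, among them HILPDA, an inhibitor of triglyceride breakdown (2.20 ± 0.27), and PPARD (0.77 ± 0.14). The 3 that fell were CIDEB (-0.89 ± 0.14), CD36 and, named after its value was seen, FABP5 (-0.87). Calls ended for TMEM97 without replicate 2, 9 or 10 (-0.24 to -0.23), ELOVL1 without replicate 1, 2 or 3 (0.22 to 0.24) and FABP5 without replicate 1, 3, 4, 5, 8, 9 or 10 (-0.93 to -0.66), and with library size alone for NR1H2 (0.13), LPCAT3 (0.05), ACSL3 (0.22) and ELOVL1 (0.04). The LXR, fatty acid and PPAR lists did not pass camera (limma), with adjusted p of 0.969, 0.997 and 0.559.

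Among 20 receptors for SAA and HDL and toll-like receptors with their adaptors, 5 rose and 8 fell. CD36, a scavenger receptor for oxidised lipoproteins and SAA, fell from 175 ± 37.3 to 30.9 ± 17.98 CPM (-2.50 ± 0.29), SCARB1, the HDL receptor, from 5.54 to 1.22 CPM (-2.20 ± 0.32), and the toll-like receptor genes TLR5 and TLR7 changed by -2.74 ± 0.30 and -3.10 ± 0.39. The 5 that rose, named after their values were seen, were FPR2, the formyl peptide receptor that binds SAA (1.74 ± 0.34), CD14, the lipopolysaccharide co-receptor (1.14 ± 0.19), TLR2 (0.99 ± 0.17), TLR8 (0.56 ± 0.12) and TLR1 (0.30 ± 0.11). Of 17 inflammasome genes 7 rose and 4 fell. IL1B, which encodes interleukin 1 beta, rose from 947 to 10397 CPM (3.46 ± 0.61, and 4.29 without replicate 8) and the inflammatory caspase genes CASP4 and CASP5 changed by 0.92 ± 0.15 and 1.66 ± 0.29, while IL18 fell together with PYCARD (-0.96), NAIP (-0.95) and GSDMD (-0.44), named after their values were seen. The median of the inflammasome list was 0.23 with TMM and turned to -0.01 without it. Calls were lost for TLR1 without replicate 3, 7 or 10 (0.24 to 0.25) and NAIP without replicate 6 or 9 (-0.85 to -0.82), and with library size alone for TLR1 (0.10) and TLR8 (0.36). Neither list passed camera (limma), with adjusted p of 0.559 and 0.559.

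Of 32 matrix remodelling genes 15 rose and 5 fell (17 and 9 with the subject as a block). MMP14, a membrane-bound collagenase, rose from 330 to 1368 CPM (2.05 ± 0.20), PLAUR, the urokinase receptor, changed by 2.19 ± 0.27 and HBEGF, a growth factor of the EGF family, by 2.59 ± 0.42. Genes that fell, named after their values were seen, included FN1 (-2.67), CTSK (-1.74), TGFBI (-1.52) and MMP25 (-1.10). This list passed camera (limma) with the subject as a block (adjusted p = 0.0456) and missed it in the fit without (adjusted p = 0.0786). With an estimated correlation its adjusted p (limma) was 0.715 with the block and 0.867 without. Of 15 coagulation genes 8 rose (10 adjusted over the list alone) and 4 fell, with rises of F3, the tissue factor that starts coagulation (2.32 ± 0.54), and of its counterpart THBD, thrombomodulin (2.46 ± 0.55). Genes that fell here, also named after their values were seen, included F13A1 (-2.25), GAS6 (-1.001) and PROS1 (-0.69). With the subject as a block F3 did not pass without replicate 4 (1.60), 7 (1.55) or 9 (1.45), and was 1.34 without replicate 6. Of 20 genes of eicosanoid synthesis and reception 3 rose and 8 fell. PTGES, which makes prostaglandin E, rose from 1.52 to 12.02 CPM (3.01 ± 0.51), while LTA4H, which makes leukotriene B, changed by -1.19 ± 0.21, PTGES2 by -0.78 ± 0.13 and the prostaglandin receptor gene PTGER2 by -0.59 ± 0.10. The other 2 that rose, named after their values were seen, were PTGS2, the inducible cyclooxygenase (3.39 ± 0.99, 5.70 with the subject as a block, 5.37 without replicate 8 and 5.46 without HDL replicate 8), and PLA2G4A, a cytosolic phospholipase (1.42 ± 0.25). Of 14 complement genes 4 rose and 6 fell (7 adjusted over the list alone), with CR1, the receptor for C3b, at -2.96 ± 0.32 and C5 at -1.76 ± 0.26 against CD55, a surface inhibitor of complement, at 1.60 ± 0.24 and C5AR1 at 1.21 ± 0.20. The other 2 that rose, named after their values were seen, were CD59 (1.25) and C3 (0.52). With library size alone as the scaling the call was lost for C3 (0.30). The coagulation, eicosanoid and complement lists did not pass camera (limma), with adjusted p of 0.405, 0.559 and 0.669.

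**Figure D4:**
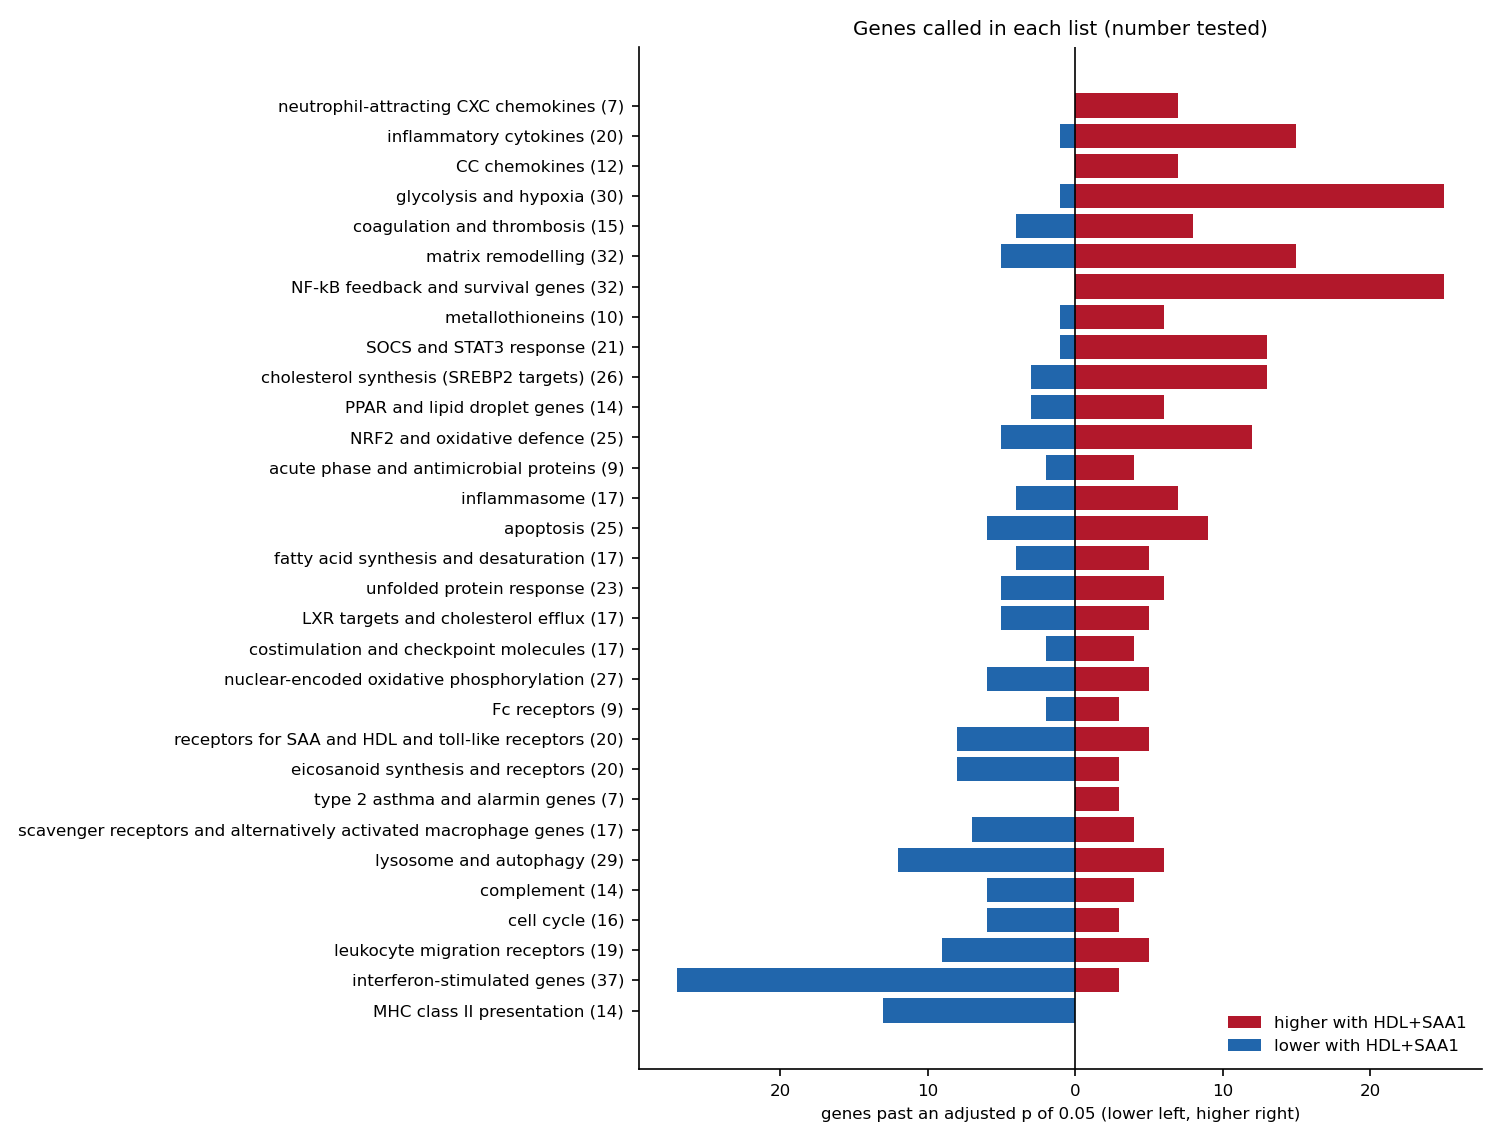
Number of genes past an adjusted p of 0.05 in edgeR (x axis, genes lower with HDL+SAA1 to the left of 0 and genes higher to the right) for each pathway list (y axis, with the number of genes tested), sorted by the list's median log2 fold change. Glycolysis and NF-kB feedback genes lie almost wholly to the right (25 higher in each), interferon-stimulated genes mostly to the left (27 lower) and MHC class II genes wholly to the left (13 lower).

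Surface and marker genes of the monocytes themselves changed as well. Of 15 classical monocyte markers 6 rose (7 adjusted over the list alone) and 6 fell, and the falls included LYZ, lysozyme (8286 to 1856 CPM, -2.16 ± 0.26), FCN1, ficolin 1 (-2.76 ± 0.44), and CSF3R, the receptor for granulocyte colony-stimulating factor (-2.001 ± 0.32). Of 13 nonclassical monocyte markers 6 rose and 4 fell, with TCF7L2 at 1.92 ± 0.27, MS4A7 at 0.91 ± 0.15 and LRRC25 at 1.05 ± 0.17. The 4 that fell, named after their values were seen, were SIGLEC10 (-2.17), CX3CR1 (-1.93), CDKN1C (-1.33) and SPN (-0.70). Of 19 leukocyte migration receptors 5 rose and 9 fell, with CX3CR1, the fractalkine receptor, at -1.93 ± 0.38 and the integrin genes ITGAL, ITGB1 and ITGB8 at 1.07 ± 0.15, 1.12 ± 0.15 and 2.38 ± 0.41. The other 2 that rose were the integrin genes ITGB3 (2.74) and ITGAV (0.72), named after their values were seen. Of 17 scavenger receptors and alternatively activated macrophage genes 4 rose and 7 fell, with the lectin gene CLEC10A at -2.80 ± 0.41, STAB1 at -1.20 ± 0.23, the iron exporter SLC40A1 at -1.76 ± 0.33 and the transglutaminase gene TGM2 at 2.67 ± 0.48. The other 3 that rose, named after their values were seen, were MARCO (1.59), CD209 (1.38) and IL4R (0.39), and IL4R did not pass with library size alone as the scaling (0.17). Of 16 markers of monocyte-derived macrophages 1 rose and 7 fell, among them GPNMB (168 to 22.1 CPM, -2.93 ± 0.47) and TREM2 (-1.97 ± 0.44), and the 1 that rose was MARCO (1.59 ± 0.43, named after its value was seen). With the subject as a block 8 of these markers fell and 4 rose, SPP1 (2.23), CCL18 (0.77) and LGMN (0.55) with MARCO, named after their values were seen. Of 17 costimulation and checkpoint genes 4 rose and 2 fell, with CD274, the checkpoint ligand PD-L1, at 1.39 ± 0.16, CD80 at 1.62 ± 0.41 and IDO1 at 1.60 ± 0.35 against PDCD1LG2, the ligand PD-L2, at -1.03 ± 0.23. The remaining 2, named after their values were seen, were LILRB1, which rose (0.86), and TNFRSF9, which fell (-0.83). The call was lost for SPN without replicate 1, 2, 4, 5, 6, 7, 9 or 10 (-0.75 to -0.61), LILRB1 without replicate 1, 2, 7, 9 or 10 (0.82 to 0.85) and without HDL replicate 8 (0.81) and TNFRSF9 without replicate 4, 6 or 9 (-0.83 to -0.69), and with library size alone for SPN (-0.86) and LILRB1 (0.63). None of these 6 lists passed camera (limma), with adjusted p from 0.559 to 0.847 and 0 at an unadjusted p under 0.05.

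The composition of the libraries was compared within subjects by an exact permutation test of the 10 paired differences, two-sided, over 16 measures with Benjamini-Hochberg adjustment. The mean log2 CPM of classical monocyte markers was lower with HDL+SAA1 in 10 of 10 subjects, by -0.62 ± 0.55 (mean ± SD of the difference, exact p = 0.00195, the smallest the test can give, adjusted p = 0.0234). Since 6 of these 15 markers rose and 6 fell, this mean rests on large falls such as those of FCN1, LYZ and CSF3R. Conventional dendritic cell markers were at -0.76 ± 0.71 (exact p = 0.00586, adjusted p = 0.0234) and neutrophil markers at -0.34 ± 0.29 (the same exact p and adjusted p), and each was higher in only 1 of 10 subjects. The neutrophil mean was low, at -1.29 log2 CPM with HDL and -1.63 with HDL+SAA1. Only 4 of its 18 genes passed the filter for testing, among them CSF3R, also a classical monocyte marker here. The neutrophil mean therefore does not show a change in neutrophils. The number of genes with at least 1 count fell from 38749 ± 5782 to 35242 ± 5480 (exact p = 0.00391, adjusted p = 0.0234). The share of counts in mitochondrial genes was 13.9% ± 1.83 with HDL and 12.5% ± 1.75 with HDL+SAA1. This difference did not pass (exact p = 0.0156, adjusted p = 0.05). Most of the share was mitochondrial ribosomal RNA, with 13.4% ± 1.75 of counts with HDL and 12.004% ± 1.74 with HDL+SAA1. It therefore says little about the mitochondrial genes that encode proteins. The total count, the share of the 10 most abundant genes and the other 9 marker lists did not pass, with adjusted p from 0.0677 to 0.951 in the exact test. These lists were of nonclassical monocytes, monocyte-derived macrophages, plasmacytoid dendritic cells, T cells, NK cells, B cells, eosinophils with basophils and mast cells, platelets, and erythrocytes. The NK cell mean was uneven between subjects, with HDL at 2.17 log2 CPM in replicate 1 and -2.56 in replicate 2. In replicate 7 it was -2.29 with HDL and 0.60 with HDL+SAA1. Without TMM scaling 9 measures passed, each lower with HDL+SAA1.

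Cytosolic ribosomal protein genes fell by small amounts, with 32 of 40 lower (34 adjusted over the list alone), 0 higher and a median log2 fold change of -0.42. RPS24 changed by -0.56 ± 0.09, RPS6 by -0.63 ± 0.11, RPL22 by -0.51 ± 0.10 and RPL11 by -0.45 ± 0.08, each lower in 10 of 10 subjects. Ribosomal protein genes have many processed pseudogenes that can share reads with them. In camera (limma) the adjusted p was 7.19e-07 (adjusted p = 0.904 with an estimated correlation). Of 13 mitochondrially encoded genes 0 passed edgeR's test at an adjusted p of 0.05 and 0 passed with the block. The largest of their values, MT-ND6 at 0.94 ± 0.69, was -0.13 without replicate 5. Of 27 nuclear genes of oxidative phosphorylation 5 rose and 6 fell (8 and 8 with the subject as a block), with NDUFA2 at 0.55 ± 0.08, NDUFS3 at -0.46 ± 0.09 and NDUFV1 at -0.64 ± 0.13. The other 4 that rose were SDHA (0.22 ± 0.05, -0.00582 with library size alone) and, named after their values were seen, COX7A2 (0.31), COX6A1 (0.26) and NDUFV2 (0.22). Significance was lost for COX6A1 without replicate 3, 4, 6, 8, 9 or 10 (0.23 to 0.26) and NDUFV2 without replicate 1, 3, 4, 5, 6 or 9 (0.18 to 0.23), and with library size alone for NDUFA2 (0.31), COX7A2 (0.10), COX6A1 (0.03) and NDUFV2 (0.01). In limma's camera the adjusted p was 0.997 for the mitochondrially encoded genes and 0.669 for the nuclear ones.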

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

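In this part the tests of swapped labels, of low depth and of lost dendritic cells and the fits with library size alone and with multicopy RNA removed were chosen after the data were seen, and the other tests before their results. A value is given here where the highest or lowest library of a group of 10 stood apart, with a gap to its nearest neighbour, as a share of the group's range, above 0.466 (Dixon's 95% value). Chance does this in about 1 of 20 groups, so 30.4 of the 608 groups looked at were due by chance and 48 met it. For the genes of the rule and the composition measures alone it was 37 of 414, with 20.7 due by chance. HDL replicate 8 had 10 of the 48, HDL replicate 7 had 9 and HDL+SAA1 replicate 5 had 13. HDL+SAA1 replicate 5 also had the lowest TMM factor of all libraries (0.581). On the axis of mean treatment difference it had the lowest position of its group (0.629). The cause was not tested. In the HDL group replicate 8 was highest, with its share of the range in brackets, in CCL4 (0.5857), CCL3 (0.4898), HILPDA (0.479), DNAJC3 (0.4873) and ITGB1 (0.5389), and lowest in PTGES2 (0.6166), MCM3 (0.5383), BCL2L11 (0.4706), NDUFV1 (0.5771) and SPN (0.5076). Replicate 7 was highest in NPC1 (0.5778), PPARD (0.5896) and BID (0.5001) and lowest in TLR5 (0.5685), ACACB (0.4766), CX3CR1 (0.4673), SERPINF1 (0.5139), PLTP (0.4704) and TLR8 (0.4944). Replicate 5 was highest in MT-ND6 (0.5332) and MT-ATP8 (0.5001), replicate 1 lowest in MT1H (0.6463) and replicate 2 lowest in ITGAL (0.4715). The mitochondrial share of counts was highest in replicate 1 (0.5513, with 18.3% against 11.8 to 14.7% in the others). On average over the HDL group, most of that share was mitochondrial ribosomal RNA. In the HDL+SAA1 group replicate 5, with the lowest total count (26424481), was highest in IL18 (0.486), C5 (0.4688), MT-ND1 (0.6644), MT-ND6 (0.645), MT-ATP8 (0.7224), MT-ND2 (0.6615), H1-3 (0.4889), CDKN1C (0.5438) and CTSK (0.484) and lowest in SLC7A11 (0.5263), BAG3 (0.4833), HSP90AA1 (0.5505) and PDIA6 (0.5306). Replicate 2 was highest in LTA4H (0.5208) and lowest in ACSL1 (0.6011), PLA2G4A (0.7182) and PTGS2 (0.5717), and replicate 6 was highest in SLC2A3 (0.4947) and lowest in CLEC10A (0.4865), CX3CR1 (0.5352) and HK3 (0.5262). Replicate 4 was highest in LPCAT3 (0.5843), replicate 10 lowest in SCARB1 (0.5086), and the mean of the platelet markers was highest in replicate 1 (0.5022).

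HDL replicate 8 lay between the groups, with high CCL3 and CCL4. A swap of labels would have put an HDL+SAA1 library on the HDL side of the midpoint, and 0 lay there. Low depth could be excluded, as 3 other HDL libraries had a lower total count. Material from an HDL+SAA1 library mixed in should give the same fraction from both directions, and the fractions were 0.414 from 146 rising genes and 0.613 from 118 falling genes, a difference of -0.199 against 0.570 (2 SD of the other 9 HDL libraries). Mixing therefore remains open, and so does a stronger response of this subject's cells to plain HDL, for which no test was possible.

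Genes of cytosolic ribosomal proteins such as RPS6 fell together, with a median log2 fold change of -0.42. Genes of like transcript length and abundance did not fall with them. For a median as low, the permutation share over 10000 random lists matched on both was 1e-04, the smallest the draws can give. The matched lists had a median of 0.22. This argues against length and abundance as the cause, but the draws took genes singly and do not allow for members that move together. With abundant noncoding RNAs removed before scaling the median was -0.43, with an SD of 0.16 over the members. TMM trims the most abundant genes in any case, so this removal could hardly move the median. It therefore cannot exclude the scaling as a cause and does not test the TMM centre. The list median was -0.65 with library size alone, where the median of all genes was -0.22, so the list lay below all genes there too. A biological change with SAA1 remains open, and so do reads shared with pseudogenes, which were not tested.

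Genes of MHC class II presentation such as HLA-DMB fell with a median of -2.48. Genes matched on transcript length and abundance did not fall with them (permutation share of matched lists 1e-04, the smallest the draws can give, with a matched median of 0.20). This argues against length and abundance as the cause, although the draws did not allow for members that move together. A loss of dendritic cells from these cultures, sorted for CD14 without CD16, would have lowered their markers at least as far, if the markers follow cell number. Within subjects the markers changed by a mean of -0.76 and the class II genes by -2.19. The gap was 1.44 (SD 1.04 over 10 subjects, and 1.57 with SD 1.09 for the tested genes alone), in that direction in 9 of 10. This argues against such a loss as the whole cause only on that condition, which was not tested, and the mean includes CD209, which rose. A share in the fall stays open, as with multicopy RNA removed the gap of the medians (1.46) was within the SD of 1.60 among the 12 markers then tested, and as the markers fell further than class II in replicate 5. In the fit without the block CLEC10A (-2.80), CD1E (-3.39) and CD1B (-2.73) fell further than the class II median (-2.48). CD1C (-1.76, named after its value was seen) fell less far in that fit and CD209 rose (1.38). With the subject as a block CLEC10A (-2.97) still fell further than the class II median (-2.49). CD1E (-2.35) and CD1B (-1.68) then fell less far and CD209 rose (1.38). Lower expression in the monocytes therefore remains a hypothesis.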

How the results depend on the processing

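The numbers of the titles pair the libraries by subject, and with the subject as a block 9823 genes changed against 8220 without it, 8183 of them shared in the same direction, and 12 lists passed, the 11 and the matrix remodelling list. Apart from the genes, the list and the counts given with the block in the text, it changed no other call of a gene named there or of a list. In the fit with the block and no filter 6301 genes were lower, against 4075, for which the cause was not tested. The scaling by library size alone, the removal of multicopy RNA and the fit without HDL replicate 8 were chosen after the data were seen. With library size alone 1471 genes were higher, against 4145, as the TMM factors were lower with HDL+SAA1 in 10 of 10 subjects, and SDHA turned from 0.22 to -0.00582. Over all settings that kept every subject, library size alone included, the count of changed genes lay between 6195 and 11762, and that of list genes, 372 in the fit reported, between 322 and 483. With each subject left out in turn, 7370 to 8441 genes changed (9070 to 9998 with the block), 3593 to 4167 were higher (4305 to 4908) and 3639 to 4274 lower (4572 to 5118), 337 to 377 list genes passed (403 to 427), 10 to 11 lists and 4 to 5 composition measures. Instead of 11 lists, 0 passed with the estimated correlation, with or without the block, 21 in fry, 31 in fry with the block and 17 with no filter, as fry asks whether a list changes at all while the cause of the others was not tested. Composition passed in 9 measures instead of 4 under CPM by library size, which lowers all levels with HDL+SAA1. The cholesterol synthesis list was the only one to lose its call when a subject was left out. Of the planned refits of 288 genes chosen for naming 8761 gave the same result, with or without a call. A call was lost in 234 (40 genes) and gained in 215 (22 genes). Of the refits chosen later 1090 gave the same result, 34 lost a call (30 genes), 19 gained one (13 genes) and 1 changed sign. With at least 26424481 counts per library, a level of 1 CPM by TMM rests on as few as 15.3 counts in a library, which limits genes near that level.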

Other observations

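In this part the scaling by library size alone was chosen after the data were seen, and the tests of neighbouring genes and of other splits were chosen before their results were seen. Genes of cell survival and stress moved in both directions and none of their lists passed camera (limma). Of 25 apoptosis genes 9 rose and 6 fell, with BCL2L11, which promotes cell death, at -1.83 ± 0.24 (log2 fold change ± SE from edgeR, n = 10 per group) and the survival gene MCL1 at 0.93 ± 0.13. Of 23 genes of the unfolded protein response 6 rose and 5 fell, with SESN2 at 1.27 ± 0.15 and the chaperone genes DNAJC3 and DNAJB9 at 1.11 ± 0.17 and 0.69 ± 0.11, against HERPUD1 at -0.41 ± 0.07 (-0.64 with library size alone as the scaling) and, named after their values were seen, SDF2L1 (-0.47), CRELD2 (-0.45), PDIA6 (-0.40) and CALR (-0.37). Of 15 heat shock genes 5 rose and 2 fell (1 adjusted over the list alone), namely BAG3 (0.75 ± 0.14), HSP90AA1 (0.46 ± 0.16), CHORDC1 (0.36 ± 0.09) and HSPE1 (-0.59 ± 0.16) and, named after their values were seen, DNAJB4 (0.35), DNAJA1 (0.32) and HSPB1 (-0.66). HSP90AA1 did not pass without replicate 3 (0.41), 6 (0.40) or 9 (0.43) or in limma-voom (0.38), and CHORDC1 did not with library size alone (0.14). Of 16 cell cycle genes 3 rose and 6 fell, with the replication genes MCM3 and MCM6 at -0.94 ± 0.13 and -0.82 ± 0.14 against CDKN1A, an inhibitor of the cycle, at 1.49 ± 0.24, TYMS at 1.002 ± 0.19 and, named after its value was seen, AURKA at 0.57. Of 25 genes of NRF2 and oxidative defence 12 rose and 5 fell, among them both subunits of the cystine transporter, SLC7A11 (1.39 ± 0.22) and SLC3A2 (1.37 ± 0.18), with falls of ME1 (-2.07 ± 0.37) and, named after their values were seen, CAT (-1.41), GCLC (-0.97), ABCC2 (-0.77) and TKT (-0.41). Of 10 metallothionein and zinc transporter genes 6 rose and 1 fell, with MT2A at 1.17 ± 0.22 and the transporter SLC39A14 at 1.57 ± 0.40 against MT1H at -0.86 (named after its value was seen). A block for subject gave 2 falls in the 10, MT1X (-0.37, named after its value was seen) with MT1H. SLC39A8 (0.60 ± 0.21) did not pass without replicate 6 (0.50) or 10 (0.56), nor did it or MT1F (0.77 ± 0.22) pass with library size alone. Calls ended for DNAJA1 without replicate 4, 6, 7 or 9 (0.27 to 0.30), DNAJB4 without replicate 1, 3, 6, 7 or 9 (0.27 to 0.35), HSPB1 without replicate 1, 3, 5, 6, 7, 9 or 10 (-0.68 to -0.53) and MT1H without replicate 2, 3, 4, 5, 6, 7 or 10 (-0.93 to -0.68) and without HDL replicate 8 (-0.77), and with library size alone for AURKA (0.37), DNAJA1 (0.11) and DNAJB4 (0.12). These 6 lists had a camera adjusted p (limma) of 0.669, 0.669, 0.559, 0.528, 0.559 and 0.528.

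Genes of host defence and degradation also split. Of 9 acute phase and antimicrobial genes 4 rose, namely PTX3, a soluble pattern recognition protein (2.57 ± 0.36), S100A9 (0.88 ± 0.22) and, named after their values were seen, S100A12 (0.68) and S100A8 (0.53). LYZ and CP (-0.42 ± 0.11, -0.37 and not passing without a filter) fell. Of 9 Fc receptor genes FCAR, the receptor for immunoglobulin A, changed by 1.55 ± 0.25, FCGR2A by 0.77 ± 0.21 and FCER1G by 0.73 ± 0.13, while FCGR1A fell (-0.94 ± 0.33, -0.89 and not passing without a filter) and so did its near-identical copy FCGR1BP (-0.81, named after its value was seen). Of 29 lysosome and autophagy genes 6 rose and 12 fell, with PSAP at -1.004 ± 0.13 and HEXA at -1.08 ± 0.16. Of 7 genes of type 2 asthma and alarmins 3 rose and 0 fell (1 adjusted over the list alone, IL17RB at -0.26, and 2 with the subject as a block, IL17RB at -0.27 and CCL24 at -0.68), namely FCER2, the low-affinity receptor for immunoglobulin E (1.99 ± 0.51), CRLF2, a subunit of the receptor for thymic stromal lymphopoietin (1.62 ± 0.43), and the interleukin 4 receptor gene IL4R (0.39 ± 0.12). Of 19 histone and small nuclear transcripts 2 rose and 3 fell (1 and 1 adjusted over the list alone), namely MALAT1 (0.56 ± 0.19) and NEAT1 (0.49 ± 0.15), which did not pass with library size alone (0.35 and 0.28), against H1-3 (-1.22 ± 0.33), H3C10 (-1.08 ± 0.40) and, named after its value was seen, H4C8 (-0.52). When subject was a block 3 of the 19 rose, RN7SK (0.33, named after its value was seen) with these 2, and 8 fell. H3C10 did not pass when replicate 1 (-1.02), 2 (-1.02), 3 (-1.003), 6 (-1.03), 9 (-1.06) or 10 (-0.96) was left out. Calls were lost for S100A12 without replicate 1, 2, 3, 5, 7, 9 or 10 (0.58 to 0.70), S100A8 without replicate 1, 2, 3, 7, 9 or 10 (0.46 to 0.53), FCGR1BP without replicate 3, 4, 6 or 9 (-0.79 to -0.72) and without HDL replicate 8 (-0.62) and H4C8 without replicate 1, 2, 3, 6 or 9 (-0.51 to -0.47), and with library size alone for IL4R (0.17), S100A12 (0.44) and S100A8 (0.30). The camera adjusted p (limma) of these 5 lists was 0.851, 0.847, 0.472, 0.761 and 0.662.

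Single markers of other blood cells moved in both directions in edgeR's test. Of 10 conventional dendritic cell markers CD209 rose (1.38 ± 0.37) and 4 fell, namely CLEC10A, CD1E, CD1B (-2.73 ± 0.91) and, named after its value was seen, CD1C (-1.76). BATF3 rose as well with the subject as a block (1.39, named after its value was seen). The call was lost for CD1C without replicate 1, 4, 5, 7, 9 or 10 (-1.82 to -1.28), and with the subject as a block (-0.98). CD1B was -1.68 with the subject as a block, and in that fit it did not pass without replicate 1 (-1.42), 6 (-1.61) or 7 (-1.48). Of 5 plasmacytoid dendritic cell markers IL3RA (1.83 ± 0.33) and LILRA4 (1.16 ± 0.39) rose and TCF4 (-1.97 ± 0.23) and SERPINF1 (-2.91 ± 0.42) fell. LILRA4 did not pass without replicate 2 (1.01) or with library size alone (0.95). Of 7 platelet markers GNG11 (3.38 ± 0.67) and PPBP (1.92, named after its value was seen) rose, and CLEC1B (-2.14 ± 0.34), CLU (-2.28 ± 0.48), SPARC (-1.83 ± 0.41) and, named after its value was seen, GP1BA (-1.52) fell. Of 4 B cell markers FCRLA (2.17 ± 0.48) and EBF1 (2.39 ± 0.58) rose and CD22 (-1.05 ± 0.20) and BANK1 (-0.88 ± 0.24) fell. Of 4 NK cell markers NCR1 (2.19 ± 0.39) rose and NCR3 (-1.43 ± 0.25), which overlaps LST1, fell. Of 4 neutrophil markers CSF3R fell and MME (1.64 ± 0.59) rose, and MME did not pass without replicate 6 (1.46) or 9 (1.54). Of 4 erythrocyte markers 0 passed in edgeR and 0 had an unadjusted p under 0.05, and HBB, at -0.40 without the block, passed in DESeq2 with it (-0.82). T cell markers had 2 tested genes, of which IL7R rose (0.91 ± 0.26) and CD5 did not pass (0.18), and markers of eosinophils, basophils and mast cells had fewer than 3. The camera adjusted p (limma) of the conventional and plasmacytoid dendritic cell, platelet, B cell, NK cell, neutrophil and erythrocyte lists was 0.669, 0.656, 0.662, 0.969, 0.847, 0.847 and 0.669.

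A hypothesis was that tandem gene families and shared loci hold the largest changes. Of the 100 protein-coding genes with the largest rises, 32 had another of the 100 within 200 kb, against a median of 4 and a highest count of 18 in 10000 random draws from 10756 protein-coding genes (permutation share 1e-04, the smallest the draws can give). The groups included the CXC chemokine genes, IL1A with IL1B, IL36G and IL1RN, LIF with OSM, CCL3 with CCL4, and SERPINB2 with SERPINB10 and SERPINB7 (3.01, 4.71 without replicate 8), while TFPI2 lies inside GNGT1. Of the 100 genes with the largest falls, 36 had such a neighbour, against a median of 4 and a highest count of 20 (permutation share 1e-04, again the smallest), and 13 of the 36 lay in the MHC class II region. The result is consistent with shared regulation of neighbouring genes, but overlapping genes and near-identical copies in these groups may share reads, so part of the excess may come from counting.

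For the count of changed genes chance could be excluded. Among 100 random splits of the 20 libraries into 10 and 10, the real one included, only the real split called as many as 8220 genes, and the highest of the others called 4408. That split kept all but 2 libraries of each group in place, and 92 of the other 99 called 0 genes. Since the numbers pair the libraries, the real labels were also compared with 99 splits that swapped the labels within some subjects and so part as many pairs. The highest of these called 6710 genes, with the labels of 1 subject swapped, and 96 called 0. For the number of gene lists chance could not be excluded, as 29 of the 100 random splits passed at least the 11 lists of the real one, and the highest of the others passed 19. Of 100 splits that swapped labels within subjects, the real one included, 38 passed as many, and the highest of the others passed 15.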
